A study of Homo sapiens with 18 samples.

How the data were processed

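RNA was measured in 18 libraries of 3 human tumour cell lines, the melanoma lines UACC-62 and SK-Mel-28 and the colorectal carcinoma line HCT-116. Per the labels, each line was infected with a lentivirus that carried either a scrambled shRNA (shControl) or an shRNA against RAB7 (shRAB7), the different lines were infected side by side, and cells were harvested on day 3 after infection. Each of the 6 groups held 3 libraries. Per the labels' protocols, poly(A) RNA was fragmented and made into libraries with Illumina's TruSeq v2 kit, which does not keep the strand, and was sequenced on a Genome Analyzer IIx. Per the submitters' processing notes, the tools were FastQC, TopHat2 2.0.4, Bowtie 0.12.7, SAMtools 0.1.16 and Cufflinks 1.3.0, on the human genome build GRCh37 (hg19). The options of these tools and the annotation's release were not available here.

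The deposited values were gene-level FPKM (fragments scaled to transcript length and library depth) that the authors made with Cufflinks, 1 table per library, per the file headers. Each table listed 52218 genes with an Ensembl identifier, a symbol, a locus on GRCh37, the FPKM and its confidence bounds, and an estimation status. Between 662 and 825 rows per library had the status FAIL and 476 had LOWDATA. All but 4 to 16 FAIL rows per library were listed at 0, and 3537 rows had FAIL in at least 1 library, so a failed estimate can be mistaken for an absent transcript. Rows whose status was not OK in every library of a fit were therefore left out of that fit, 1542 rows in SK-Mel-28, 1627 in UACC-62 and 1638 in HCT-116. A total of 77 gene identifiers were listed at more than 1 locus, and each locus was kept as a row of its own.

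The tables give no read counts. Cufflinks' bounds allowed a fragment count to be implied for each gene, under the assumption that the bounds follow counting error. These implied counts added up to 2440000 to 4950000 fragments per library, and 29.6% to 35.9% of those below 100 lay within 0.01 of a whole number. The depth is therefore known only as this estimate. FPKM totals lay between 490614 and 568144 per library.

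Groups and replicate numbers came from the labels. Every test was a limma linear model on log2(FPKM + 1), with empirical Bayes moderation, a mean-variance trend, two-sided p-values and Benjamini-Hochberg adjustment at 0.05. Genes needed a mean of at least 1 FPKM over the libraries of the fit. The pseudocount of 1 shrinks the log2 change of genes with low values, so their changes are understated. shRAB7 was compared with shControl within each line. The difference between responses was tested as an interaction, the mean of the melanoma responses minus that of HCT-116 over all 18 libraries, and SK-Mel-28 minus UACC-62 over the melanoma libraries. These fits required a mean of 1 FPKM in each line concerned. The control libraries of the melanoma lines were also compared with those of HCT-116. Nothing in the labels says that replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

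The same replicate numbers occur in all 6 groups. Deviations from the group mean were correlated between the control and the shRAB7 library of the same number at r of 0.187 to 0.512 across genes, and all 9 pairs matched best within their own number, against at most 0.170 for other numbers. The labels do not state what a number stands for, so the pairing comes from the shared numbers and this check. The design without the replicate block was fixed as the primary one. A second fit with the replicate number as a block is given wherever it changed a call or moved a count by over 1.5 times.

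A total of 22 gene lists with 801 genes were fixed before the data were examined, and 793 of these genes matched a row. Lists with at least 5 tested members were tested with limma's camera at an inter-gene correlation of 0.01, again with the correlation estimated from the data, and with fry. Members called were counted over all genes tested and adjusted over the list alone. The genes named were fixed by rule: RAB7A in every line, the 10 largest changes each way among called genes with at least 5 FPKM in the higher group and no overlap between the 3 and 3 libraries, symbols of clones and small RNAs left out, and the 2 list members with the smallest adjusted p among those called. For the interaction and the control comparison the rule took the 6 largest each way. Genes named outside this rule are marked as such. Not every list member that the rule selects is reported. Genes whose locus overlaps another annotated gene are given as uncertain, since reads without strand cannot be told apart there.

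The methods were tested on simulated data with the same groups. Changes in single genes were put only into genes with means well above the minimum of 1 FPKM, 100 genes for each size. Recovery among genes near that minimum was therefore not measured. In UACC-62, SK-Mel-28 and HCT-116, simulated changes of 1 on the log2 scale were recovered for 74%, 64% and 69% of genes, and changes of 2 for 98%, 94% and 94%. With the replicate block the shares were 72%, 61% and 62%, and 94%, 95% and 93%. For the interaction between the melanoma lines and HCT-116 72% and 99% were recovered, or 79% and 100% with the block. For SK-Mel-28 against UACC-62 they were 50% and 93%, or 59% and 95% with the block, and for the control comparison 84% and 97%. With nothing changed, 0 genes were called in each of these comparisons. Beside the changed genes, 0 to 8 unchanged genes were called in the line and response comparisons. In the control comparison 19 were, or 15 with the block. Genes were drawn independently in these simulations, so false calls from replicate differences shared by many genes were not measured. A simulated shift of 0.5 in 1 list was called, and 0 of the 20 other lists were. Genes were drawn independently in it, so it does not test lists whose members vary together.

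Alternatives were other pseudocounts and filters, median-of-ratios scaling, quantile normalization, rows of other status kept, no mean-variance trend, 1 fit for all libraries, the replicate block and each library left out in turn. After the data were seen, the same choices were run together with the block, failed estimates were treated as missing, and the HCT-116 comparisons were repeated without a control library that held melanoma transcripts. The shRNA target was matched to GENCODE v29 transcripts on GRCh38, and no coordinate was converted between builds. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, models were fitted with R 4.3.3 and limma 3.58.1, and plots were drawn with matplotlib 3.10.9.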

Results

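Gene expression after lentiviral knockdown of RAB7 was profiled by poly(A) RNA sequencing in 2 melanoma lines, UACC-62 and SK-Mel-28, and in the colorectal carcinoma line HCT-116. The design asks how RAB7-depleted cells differ from control cells and whether melanoma and non-melanoma lines respond alike. Each line had 3 libraries with a scrambled shRNA and 3 with the RAB7 shRNA, all from day 3 after infection. Between 13769 and 14786 genes reached 1 FPKM per library, and implied depths were 2440000 to 4950000 fragments. Replicates correlated at r of 0.970 to 0.987 across genes, and differed by 1.45 to 4.59 times the chi-square expected from counting error alone.

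The HCT-116 control library of replicate 1 stood apart, since it held transcripts of the melanoma lines. SPARC, which encodes a matrix glycoprotein, was at 150 FPKM there against 8.52 to 22.1 in the other 5 HCT-116 libraries. S100B, a calcium-binding protein of the melanocyte lineage, was at 36.1 against 2.05 to 5.31, and TYR, the tyrosinase of melanin synthesis, at 7.17 against 0.271 to 1.06. Over 70 genes abundant in UACC-62 controls and near 0 in HCT-116, this library held a median of 7.39% of the UACC-62 level (quartiles 6.03% and 8.93%), and the other 5 held 0.379% to 1.08%. The share of the SK-Mel-28 level was lower and more spread, with a median of 3.43% over 57 genes (quartiles 1.43% and 8.19%). The pigment protein gene PMEL, whose status was not OK in every library, was at 1929 FPKM in SK-Mel-28 controls and 2.02 in UACC-62 controls. It was at 4.27 in the HCT-116 control library of replicate 1 and at 2.67 to 6.72 in the other 5. These genes were chosen after their values were seen. In the melanoma libraries the median share of another line's genes was at most 1.11%.

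RAB7A, which encodes the small GTPase that directs traffic from late endosomes to lysosomes, was lower with the RAB7 shRNA in every library of all 3 lines (ENSG00000075785, GRCh37 chromosome 3, 128444965 to 128533639). In UACC-62 it fell from 802 ± 49.4 to 72.4 ± 45.7 FPKM (SD, n = 3), or 9.03% of the control level (log2 change −3.62, SE 0.34; limma adjusted p = 0.0201). In SK-Mel-28 it fell from 374 ± 68.8 to 102 ± 32.6 FPKM, or 27.4% (log2 change −1.89, SE 0.22; adjusted p = 0.0258). In HCT-116 the means were 198 ± 6.35 and 107 ± 8.64 FPKM, or 54.2% (log2 change −0.88, SE 0.10). The adjusted p was 0.127, or 0.0731 with the replicate block, so the gene did not pass over all genes tested in that line. Its limma p before adjustment was 9.65e-06, or 5.58e-06 with the block. The target given for the shRNA, GATTGACCTCGAAA, matched RAB7A transcripts and those of 0 other genes, within the coding part of exon 4 of 6 (GRCh38 chromosome 3, 128806569 to 128806582). Control levels differed too, and RAB7A was higher in the melanoma controls than in HCT-116 controls by 1.45 on the log2 scale (SE 0.12; adjusted p = 8.6e-07).

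**Figure D1:**
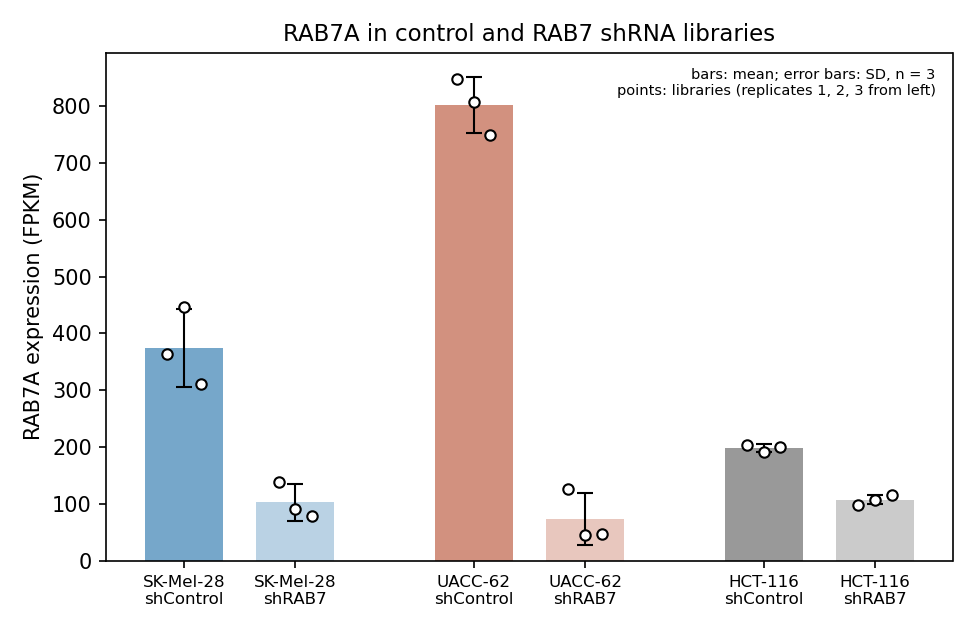
RAB7A expression in FPKM (vertical axis, from 0) in the 6 groups; bars are means, error bars the SD of 3 libraries, points single libraries. Control means were 374, 802 and 198 FPKM in SK-Mel-28, in UACC-62 and in HCT-116, and shRAB7 means were 102, 72.4 and 107 FPKM.

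In SK-Mel-28, few single genes passed the test. At a preset correlation between genes, lists of the invasive melanoma state and of cell division were lower after knockdown and lists of pigment-lineage and lysosomal genes were higher. With an estimated correlation none of these lists was called (adjusted p = 0.627), and over all genes 0 members of the cell division and lysosomal lists were. Without the replicate block 3 genes fell and 0 rose, of 12607 tested (838 had an unadjusted p under 0.05). These were RAB7A, TGOLN2, which encodes an integral protein of the trans-Golgi network (50.8 ± 7.63 to 18.1 ± 0.749 FPKM, n = 3; log2 change −1.43, SE 0.15; adjusted p = 0.0258), and hsa-mir-1974, named outside the rule, which rests on a median of 1 implied fragment, overlaps another gene and was listed at 0 in all shRAB7 libraries. With the replicate block 42 genes passed, 12 higher and 30 lower. COX7C, a subunit of cytochrome c oxidase, rose from 110 ± 21.1 to 251 ± 35.5 FPKM (log2 change 1.20, SE 0.11; adjusted p = 0.00223), and KDM3A, a hypoxia-induced histone demethylase (log2 change 0.85, SE 0.13; adjusted p = 0.0335), and C9orf86, whose locus overlaps other genes (0.91), rose as well. Among the genes that fell were CPA4, a carboxypeptidase (log2 change −1.40), AKIRIN1 (−1.04), C18orf32 (−1.03), and C12orf32 (−1.31) and NEDD8-MDP1 (−0.94), both uncertain because their loci overlap other genes. The counts rested on single libraries. The 3 calls became 5 without shControl 1, 14 without shControl 3, and 0 without shControl 2, shRAB7 2 or shRAB7 3, and the 42 became 16, 0 and 339 without the pair of replicate 1, 2 and 3.

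Camera called 9 of 20 lists in SK-Mel-28, and 7 with the block. With an estimated correlation none was called, with an adjusted p = 0.627 for each of the 9. The list of the invasive or dedifferentiated melanoma state had a median log2 change of −0.31 over 31 members, 27 of them negative (adjusted p = 1.05e-06 without an estimated correlation). With the block 2 of its members fell, or 14 adjusted over the list alone, and 29 were not called. CYR61, a matricellular growth regulator, fell from 21.5 ± 7.09 to 7.69 ± 1.58 FPKM (log2 change −1.35, SE 0.22; adjusted p = 0.0356), and PLAUR, the urokinase receptor, fell by 0.86 on the log2 scale. The melanocyte lineage list had a median of 0.26 over 33 members, 28 of them positive (adjusted p = 4.9e-05). In it 1 member rose with the block and 1 fell, or 13 and 1 adjusted over the list alone. The endothelin receptor gene EDNRB rose by 0.69 (SE 0.12) and RAB38, a GTPase of melanosome biogenesis, fell by 1.16 on the log2 scale (SE 0.12; adjusted p = 0.00278). The list of lysosomal membrane proteins and hydrolases had a median of 0.14, with 40 of 51 members positive (adjusted p = 0.000686) and 0 called in either fit over all genes, or 1 higher adjusted over the list alone. The extracellular matrix list had a median of 0.19 over 22 members (adjusted p = 0.0337), also with 0 called, or 3 higher with the block adjusted over the list alone.

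The cell cycle and DNA replication list was lower in SK-Mel-28, with a median log2 change of −0.22 and 45 of 47 members negative (adjusted p = 4.26e-07, and 0.627 with an estimated correlation). Over all genes 0 members were called in either fit, and 4 fell with the block adjusted over the list alone. The medians of its 3 pairs were −0.21, −0.22 and −0.21, and fry, which tests whether members move one way on balance and does not compare them with other genes, gave an adjusted p = 0.0258 with the block. NF-kB targets and inflammatory cytokines had a median of −0.25 over 19 members (adjusted p = 0.00115); with the block 1 member passed, the cytokine gene LIF at −1.23, whose locus overlaps another gene, and 5 fell adjusted over the list alone. Cholesterol and lipid synthesis genes (median −0.12 over 26 members, adjusted p = 0.0461) and replication-dependent histones (−0.10 over 12 members, adjusted p = 0.0277) were no longer called with the block (adjusted p = 0.0655 and 0.0512). The 14 mitochondrially encoded transcripts had a median of −0.38 (adjusted p = 0.000743) with 0 called, and their pair medians were −0.42, −0.69 and 0.06. All rows of the mitochondrial chromosome, a wider set than this list, made up 10.7%, 11.9% and 6.72% of all FPKM in the control libraries. In each shRAB7 library these rows made up at least 6.84%. With a library left out, the lysosomal, invasive and cell cycle lists of SK-Mel-28 stayed called. The melanocyte list (0.16, adjusted p = 0.158) and NF-kB targets (−0.13, adjusted p = 0.136) were lost without shRAB7 1, and the matrix list without shControl 1 or shRAB7 3 (adjusted p = 0.379 and 0.365). Mitochondrially encoded transcripts were lost without shControl 1, shControl 2 or shRAB7 3 (adjusted p = 0.0539 to 0.178) and histones without shControl 1 or shRAB7 1 (0.0598 and 0.167). Cholesterol and lipid synthesis was lost without any library but shControl 1 and shRAB7 2 (0.0684 to 0.248). With all libraries, quantile normalization lost the mitochondrial list (−0.12, adjusted p = 0.219), and the matrix list was lost with no filter, with genes of other status kept and in 1 fit of all libraries (adjusted p = 0.302, 0.121 and 0.2). Cholesterol and lipid synthesis was lost in 4 further alternatives (adjusted p = 0.0528 to 0.105) and histones in 2 (0.0785 and 0.105). With the block, the matrix list was lost without pair 1 or 3 (0.0619 and 0.224), with no filter (0.245) and in 1 fit (0.0987), NF-kB targets without pair 1 (0.0619) and the mitochondrial list without pair 2 (0.111) and with quantile normalization (0.124).

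In UACC-62, lists of DNA replication and mitosis and of cholesterol and lipid synthesis were lower after knockdown at a preset correlation between genes, and lysosomal, matrix, chaperone and hypoxia lists were higher. None of these lists was called with an estimated correlation (adjusted p = 0.668 to 0.698). Without the replicate block 8 genes fell and 0 rose, of 12949 tested (1529 had an unadjusted p under 0.05). Beside RAB7A these were SYNGR2, a vesicle membrane protein (21.3 ± 1.81 to 6.72 ± 1.15 FPKM, n = 3; log2 change −1.54, SE 0.15; adjusted p = 0.0201), TGOLN2 (51.2 ± 0.812 to 17.7 ± 3.38 FPKM; −1.50, SE 0.14), CCDC58 (−1.05), AKIRIN1 (−0.89), ACLY, the ATP citrate lyase that supplies acetyl-CoA for lipid synthesis (106 ± 0.718 to 64.9 ± 3.45 FPKM; −0.71, SE 0.09), and, named outside the rule, AL138781.1 and RP11-161H23.5. With the replicate block 670 genes passed, 279 higher and 391 lower. The largest rises by the naming rule were in TRIM48 (1.26), NSG1, an endosomal protein of neurons whose locus overlaps another gene (1.21), the pseudogene RPL23AP7 (1.21, uncertain since it shares sequence with its parent gene), GPR155 (1.04), ITIH5L (1.01) and ETNK2, an ethanolamine kinase (1.01). GRAMD3 (0.99), COX7C (0.97), PPP2R2B (0.95) and the matrix metalloproteinase gene MMP15 (0.94) followed. The largest falls by the naming rule, after RAB7A, were in ANLN, a scaffold of cytokinesis whose locus overlaps another gene (−1.69), RAB38 (−1.59), SYNGR2 (−1.54), the DNA repair and replication genes RAD51AP1 (−1.53) and CDC45 (−1.52), and TGOLN2 (−1.50). C12orf32, with overlapping loci (−1.48), DLX2 (−1.40) and the replication gene CDC6 (−1.29) followed.

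Counts in UACC-62 depended on single libraries. RAB7A stayed at 125 FPKM in the shRAB7 library of replicate 1, against 45.5 and 46.4 in the other 2. Without that library 361 genes were called instead of 8, without shControl 1 there was 1, and without any other library 0. The 670 calls with the block became 739, 32 and 154 without the pair of replicate 1, 2 and 3, and 0 with no filter on low values or with no mean-variance trend.

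Camera called 7 of 21 lists in UACC-62, and 8 with the block. With an estimated correlation none held, with adjusted p = 0.668 to 0.698 for the 7 and 0.402 to 0.688 for the 8. The cell cycle list fell most, with a median log2 change of −1.04 and all 45 members negative (adjusted p = 2.05e-16 at the preset correlation). With the block 39 members fell, 0 rose and 6 were not called, and 44 fell adjusted over the list alone; without the block these were 0 and 3. Examples were CDC6, which loads the replicative helicase (30.9 ± 2.55 to 12.6 ± 4.92 FPKM; SE 0.15; adjusted p = 0.011), and MCM4, a subunit of that helicase (105 ± 30.3 to 54.7 ± 29.4 FPKM; −1.01, SE 0.12). The pair medians were −0.48, −1.25 and −1.37. Replicate 1, with the control and the shRAB7 library averaged, itself stood 1.08 higher on this list than replicates 2 and 3 (median log2 difference), a shift as large as that between the shRNAs. The cholesterol and lipid synthesis list had a median of −0.30 with 22 of 26 members negative (adjusted p = 0.000114). In it 7 members fell with the block and 19 were not called, or 14 fell adjusted over the list alone; without the block ACLY alone was called, and 3 adjusted over the list alone. With the block, fry gave an adjusted p of 0.0302 for this list and of 0.114 for the cell cycle list.

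The lysosomal list was higher in UACC-62, with a median of 0.15 and 42 of 55 members positive (adjusted p = 4.91e-05, and 0.668 with an estimated correlation). With the block 7 members rose and 48 were not called, or 12 rose and 1 fell adjusted over the list alone. SCARB2, a lysosomal membrane receptor, rose from 92.3 ± 7.38 to 141 ± 14.5 FPKM (log2 change 0.60, SE 0.06; adjusted p = 0.00929), and SMPD1, the acid sphingomyelinase, from 34.1 ± 1.97 to 51.3 ± 4.04 FPKM (0.58, SE 0.10; adjusted p = 0.0224). The matrix list had a median of 0.18 over 26 members (adjusted p = 0.0136; 5 rose and 1 fell with the block, 9 and 1 over the list alone), with SPARC at 0.64 and ITGB3, the integrin beta 3 subunit, at 0.60, both with overlapping loci. The hypoxia and glycolysis list had a median of 0.18 over 31 members (adjusted p = 0.000802; 5 rose with the block, 11 adjusted over the list alone), with ADM, which encodes adrenomedullin (0.72), and NDRG1 (0.42). Endoplasmic reticulum chaperones had a median of 0.17 over 26 members (adjusted p = 0.00528; 5 rose and 1 fell with the block, 8 and 1 over the list alone), with CALR (0.24) and HSP90B1 (0.23, overlapping locus). The p53 target list had a median of 0.13 over 30 members (adjusted p = 0.00392), and with the block CDKN1A, the inhibitor of cyclin-dependent kinases, rose (0.69, SE 0.09; adjusted p = 0.0147) while 29 members were not called, or 8 rose and 4 fell adjusted over the list alone. The mitochondrially encoded list (median 0.17 over 14 members) was called with the block alone (adjusted p = 0.0101, and 0.0538 without it), with MT-ND6 (0.45) and MT-CO2 (0.27) higher. Without the block, chaperones were not called without shControl 1 (0.11, adjusted p = 0.356), shRAB7 2 (0.11, adjusted p = 0.0998) or shRAB7 3 (0.14, adjusted p = 0.149). The matrix list was not called without shRAB7 2 (0.09, adjusted p = 0.108), with no filter (0.07, adjusted p = 0.0655), with quantile normalization (adjusted p = 0.0503) or in 1 fit of all libraries (adjusted p = 0.2). The other 5 called lists stayed called with any library left out. With the block, the matrix list was lost without pair 2 (adjusted p = 0.0555) and in 1 fit (0.103), p53 targets without pair 3 (0.0753), and the mitochondrial list without pair 3 (0.04, adjusted p = 0.5) and with quantile normalization (0.00, adjusted p = 0.983).

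The invasive list was not called in UACC-62 (median −0.15 over 39 members, adjusted p = 0.169), although with the block CYR61 fell by 0.87 and PLAUR by 0.70 on the log2 scale (3 members fell and 1 rose; 4 and 3 adjusted over the list alone). The melanocyte lineage list split (median 0.12, mean −0.03, adjusted p = 0.443), with 4 members higher and 4 lower with the block, or 10 and 6 adjusted over the list alone; S100B rose by 0.79 and RAB38 fell. The lists nearest to RAB7 itself were called in none of the 3 lines. Late endosome machinery had medians of −0.02, −0.01 and −0.03 in SK-Mel-28, in UACC-62 and in HCT-116, with SNX1, a sorting nexin of the retromer (0.37), called in UACC-62 with the block, and Rab GTPases had medians of −0.04, 0.02 and 0.00, with RAB38 called in both melanoma lines with the block. V-ATPase subunits had medians of 0.09, 0.01 and 0.00, and ATP6AP2 (0.34) was called in UACC-62 with the block.

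**Figure D2:**
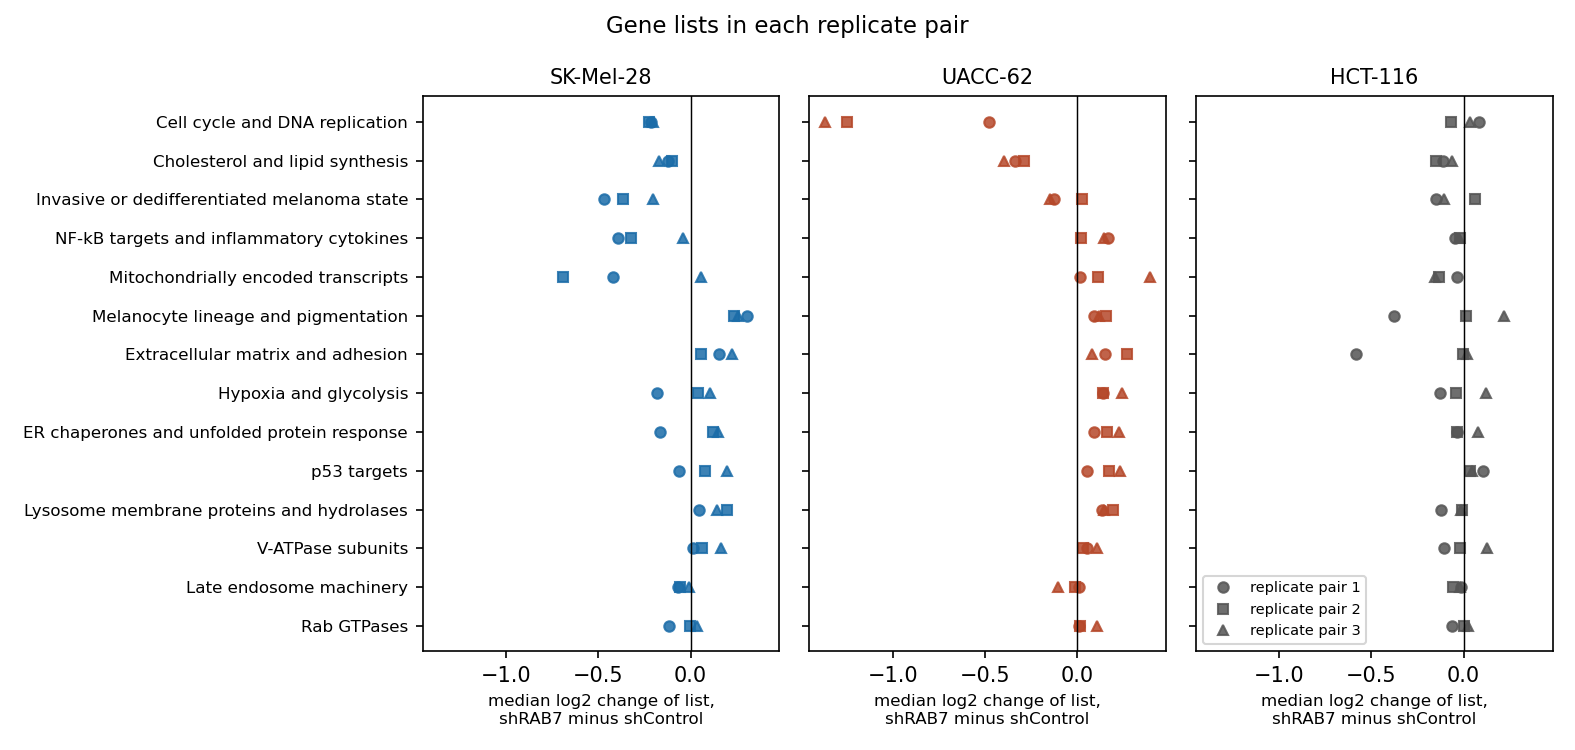
Median log2 change (shRAB7 minus shControl, horizontal axis) of 14 gene lists in each replicate pair (circles, squares and triangles for pairs 1, 2 and 3) of the 3 lines. The cell cycle list sat at −0.48, −1.25 and −1.37 in UACC-62, and in HCT-116 the pair with the library that held melanoma transcripts stood apart in the melanocyte (−0.38) and matrix (−0.59) lists.

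In HCT-116 limma called 0 of 13117 genes, without the replicate block (186 had an unadjusted p under 0.05) and with it (707). Over the 6271 genes whose control level was no higher in either melanoma line than in HCT-116, which the melanoma transcripts can hardly move, it again called 0 in both fits (84 and 314 at an unadjusted p under 0.05). On the same kind of genes 239 were called in UACC-62 and 15 in SK-Mel-28 with the block. Without shRAB7 3 a single gene was called, RAB40A, named outside the rule (log2 change 3.34; adjusted p = 0.0431).

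Camera called 3 of 22 lists in HCT-116, all lower. Cholesterol and lipid synthesis genes had a median log2 change of −0.10, with 26 of 29 members negative (adjusted p = 0.000303, and 0.485 with an estimated correlation), 0 members called over all genes and 4 lower with the block adjusted over the list alone. Its pair medians were −0.11, −0.15 and −0.06. Mitochondrially encoded transcripts had a median of −0.12 over 14 members and the matrix list −0.20 over 23 (adjusted p = 0.0304 each, and 0.987 with an estimated correlation), with 0 members called. The matrix pair medians were −0.59, 0.00 and 0.02, the first from the pair whose control held melanoma transcripts. Without that control library the matrix list was at −0.07 (adjusted p = 0.81), the mitochondrial list at −0.12 (adjusted p = 0.175), and cholesterol and lipid synthesis at −0.13 (adjusted p = 0.00219, and 0.981 with an estimated correlation). With the block and without that pair the mitochondrial list was called (−0.16, adjusted p = 0.0283, and 0.966 with an estimated correlation). With the block the matrix list was no longer called (adjusted p = 0.0561), and p53 targets were called higher (median 0.09 over 32 members, adjusted p = 0.0221, and 0.851 with an estimated correlation), but not without that pair (adjusted p = 0.458). Without other libraries too, the matrix list (shControl 2, shRAB7 1 or shRAB7 3; adjusted p = 0.173 to 0.483) and the mitochondrial list (shControl 3, shRAB7 2 or shRAB7 3; adjusted p = 0.0561 to 0.44) were not called. With all libraries, the matrix list was lost in 4 further alternatives (adjusted p = 0.0549 to 0.116) and the mitochondrial list with quantile normalization and in 1 fit of all libraries (0.138 and 0.176). With the block the mitochondrial list was lost with these same choices (0.171 and 0.0942) and without pair 2 or 3 (0.183 and 0.195). The melanocyte list, at −0.12 over 22 members (adjusted p = 0.188), was at 0.05 without the control library that held melanoma transcripts. Lysosomal genes (−0.07), the invasive list (−0.07), chaperones (−0.04), hypoxia (−0.03) and NF-kB targets (−0.01) were not called. The intestinal epithelial markers were at 0.03 over 16 members (adjusted p = 0.932). The cell cycle list was at 0.01 over 46 members (adjusted p = 0.976), with 0 called.

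The melanoma lines shared part of their response. RAB7A and TGOLN2 were called lower in both without the block. With it 17 genes were shared, COX7C higher and 16 lower, among them RAB38, AKIRIN1, CYR61, PLAUR and C18orf32, and 0 went in opposite directions, where independent lists would share 0.179 and 0.923. Of the 620 genes called in UACC-62 with the block and tested in SK-Mel-28, 529 had the same sign there, and of 576 tested in HCT-116, 291 had. Of the 247 tested in HCT-116 that were no higher in either melanoma line, 142 had the same sign (57.5%). Across genes, which are not independent replicates, the log2 changes of SK-Mel-28 and UACC-62 correlated at Pearson r = 0.303 (Spearman 0.299), those of SK-Mel-28 and HCT-116 at 0.036 (0.040), and those of UACC-62 and HCT-116 at 0.009 (0.021). The lines shared no libraries. The values for HCT-116 over all genes include the control library that held melanoma transcripts.

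**Figure D3:**
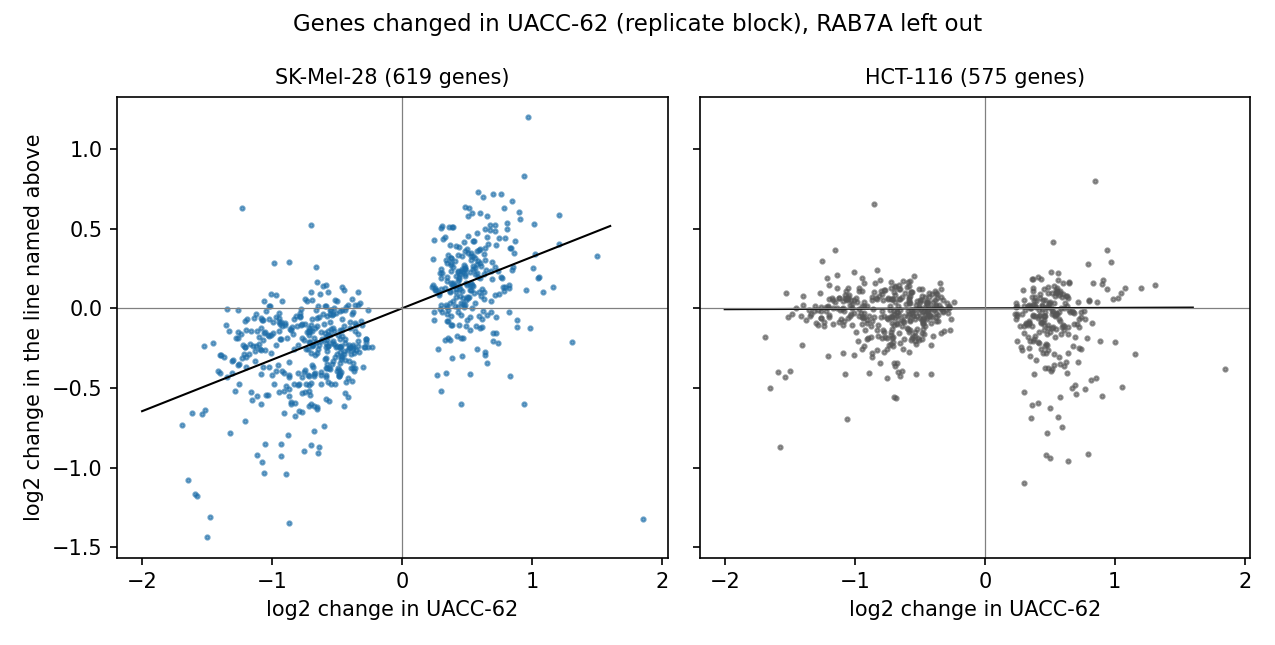
Log2 change in UACC-62 (horizontal axis) of the genes called there with the replicate block, against their log2 change in SK-Mel-28 (619 genes) and HCT-116 (575 genes); points are genes, lines are slopes through 0, the mean over 3 pairs, RAB7A is left out. The slope was 0.323 in SK-Mel-28 and 0.00285 in HCT-116. In HCT-116 the pair slopes were −0.137, 0.117 and 0.0288, the first from the pair whose control held melanoma transcripts.

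The responses of the melanoma lines and of HCT-116 were compared directly over 9980 genes. Without the replicate block 0 genes differed (410 had an unadjusted p under 0.05). With it 6 differed, each at an adjusted p of 0.0389, 2 higher in the melanoma lines and 4 lower. RAB7A (difference −1.87, SE 0.27), TGOLN2 (−1.07, SE 0.13) and RAD51AP1, a DNA repair gene (−0.98, SE 0.14), were lower, as was RAD54L (−1.16, SE 0.17), whose locus overlaps another gene. COX7C (0.79, SE 0.11) and TMX4, a thioredoxin-related membrane protein (0.79, SE 0.11), were higher. Without the HCT-116 pair of replicate 1 the 6 differences ranged from −1.95 for RAB7A to 0.83 for COX7C and 0 genes were called. Under median-of-ratios scaling 3 genes were called, 2 higher and 1 lower.

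Of 20 lists, 4 differed between the melanoma lines and HCT-116. The cell cycle list was at −0.63 with all 42 members negative (adjusted p = 1.83e-13), the lysosomal list at 0.22 with 40 of 44 positive (adjusted p = 9.19e-08), the matrix list at 0.36 over 15 members (adjusted p = 8.05e-05) and the melanocyte list at 0.30 over 13 (adjusted p = 0.00462); each had an adjusted p = 0.619 with an estimated correlation. In these lists 0 members were called over all genes, and with the block adjusted over the list alone 33 cell cycle members were lower, 5 matrix members higher, and 2 melanocyte members higher and 2 lower. Without the HCT-116 control library that held melanoma transcripts, the cell cycle (−0.61, adjusted p = 3.23e-11) and lysosomal lists (0.19, adjusted p = 9.64e-06) were still called, and the matrix (0.24, adjusted p = 0.057) and melanocyte lists (0.25, adjusted p = 0.517) were not. With an estimated correlation each of these lists had an adjusted p = 0.965 in that fit. With the block and without that pair the matrix list was called (0.19, adjusted p = 0.00698, and 0.192 with an estimated correlation). The invasive list was then called too (−0.25, adjusted p = 0.00698, and 0.622 with an estimated correlation), which it was not without the block (adjusted p = 0.153). With the block hypoxia was called too (0.10, adjusted p = 0.0286, and 0.907 with an estimated correlation), but not without that pair (adjusted p = 0.388), without SK-Mel-28 pair 2 or 3 (0.0661 and 0.11) or without UACC-62 pair 1 or 3 (0.0774 and 0.0728). The melanocyte list was also lost with a minimum of 5 FPKM (adjusted p = 0.145, and 0.138 with the block) and, with the block, without UACC-62 pair 2 (0.0884) or HCT-116 pair 1 (0.388).

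Between SK-Mel-28 and UACC-62 limma called 0 of 11200 genes as responding differently, without the block (467 at an unadjusted p under 0.05) and with it (1256). RAB7A differed by 1.73 (SE 0.45; adjusted p = 0.997, and 0.182 with the block). Of 20 lists, 7 differed, and 11 with the block. The cell cycle list was less reduced in SK-Mel-28 (difference 0.84, 42 of 43 members positive; adjusted p = 1.77e-13, and 0.724 with an estimated correlation), with 36 members passing with the block adjusted over the list alone. Lower in SK-Mel-28 were the invasive list (−0.29, adjusted p = 0.00362), NF-kB targets (−0.19, adjusted p = 0.0267), hypoxia (−0.21, adjusted p = 0.00324) and mitochondrially encoded transcripts (−0.44, adjusted p = 6.32e-06). Cholesterol and lipid synthesis (0.26, adjusted p = 0.0147) and the ATF4 list (0.18, adjusted p = 0.0388) were higher, and each of these lists had an adjusted p = 0.724 with an estimated correlation. The 4 further lists called with the block were melanocyte (0.21), p53 targets (−0.12), chaperones (−0.10) and histones (−0.22), with adjusted p = 0.348 to 0.678 with an estimated correlation. Without the block, the cell cycle and mitochondrial lists alone stayed called with any library left out. Without UACC-62 shControl 1 or SK-Mel-28 shRAB7 1, the invasive, NF-kB, hypoxia and cholesterol lists were lost (adjusted p = 0.0593 to 0.531). The invasive list was also lost without SK-Mel-28 shControl 2 or UACC-62 shRAB7 3 (0.099 and 0.0565), and NF-kB targets without SK-Mel-28 shControl 2 (0.108). Without UACC-62 shRAB7 2 or 3, NF-kB targets and the cholesterol list were lost (0.145 to 0.27). The ATF4 list was lost without SK-Mel-28 shControl 1 or 3, SK-Mel-28 shRAB7 2 or 3, UACC-62 shControl 2 or 3 or UACC-62 shRAB7 1 (0.0863 to 0.713). With all libraries, quantile normalization lost the hypoxia and mitochondrial lists (0.0552 and 0.515), and keeping genes of other status lost the ATF4 and cholesterol lists (0.146 and 0.0944). With the block, p53 targets, chaperones, NF-kB targets and histones were lost without SK-Mel-28 pair 1 (0.0721 to 0.474), p53 targets and chaperones without UACC-62 pair 3 (0.314 and 0.115), p53 targets without UACC-62 pair 2 (0.0529) and histones without UACC-62 pair 1 (0.0642). The ATF4 list was then lost without SK-Mel-28 pair 2 or 3 or UACC-62 pair 1 or 2 (0.0634 to 0.253). With the block, quantile normalization lost the mitochondrial list (0.348), chaperones (0.151) and p53 targets (0.0559), and a minimum of 5 FPKM lost the ATF4 list (0.0612) and p53 targets (0.0637).

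Beside RAB7A, 16 genes had all 3 shRAB7 libraries below all 3 control libraries in each of the 3 lines, and 6 had them above, of 9980 genes tested. Chance separates 10% of genes in a single line, and 0.0125% in a given direction in 3 independent lines. On the higher side, other regroupings of the libraries within lines reached 29 genes, more than the 6 found. RAB38 had log2 changes of −1.16, −1.59 and −0.40 in SK-Mel-28, in UACC-62 and in HCT-116, C18orf32 −1.03, −1.06 and −0.69, and AKIRIN1 −1.04, −0.89 and −0.41. SYNGR2 was at −0.66, −1.54 and −0.43, LYPLA2, an acyl-protein thioesterase, at −0.63, −0.65 and −0.43, and SNAP23, a SNARE of membrane fusion, at −0.27, −0.20 and −0.23. COX7C was at 1.20, 0.97 and 0.29, and SYNJ2BP, a protein of the mitochondrial outer membrane, at 0.81, 0.41 and 0.45. None of the 22 genes passed the test in HCT-116, where the smallest adjusted p with the block was 0.32, for C18orf32. LYPLA2, SNAP23, SYNJ2BP and the set itself were chosen after their values were seen. The HCT-116 values include the control library that held melanoma transcripts, which can read higher for genes abundant in the melanoma lines. The set, with the melanocyte list gene RAB38, was not recomputed without that library.

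**Figure D4:**
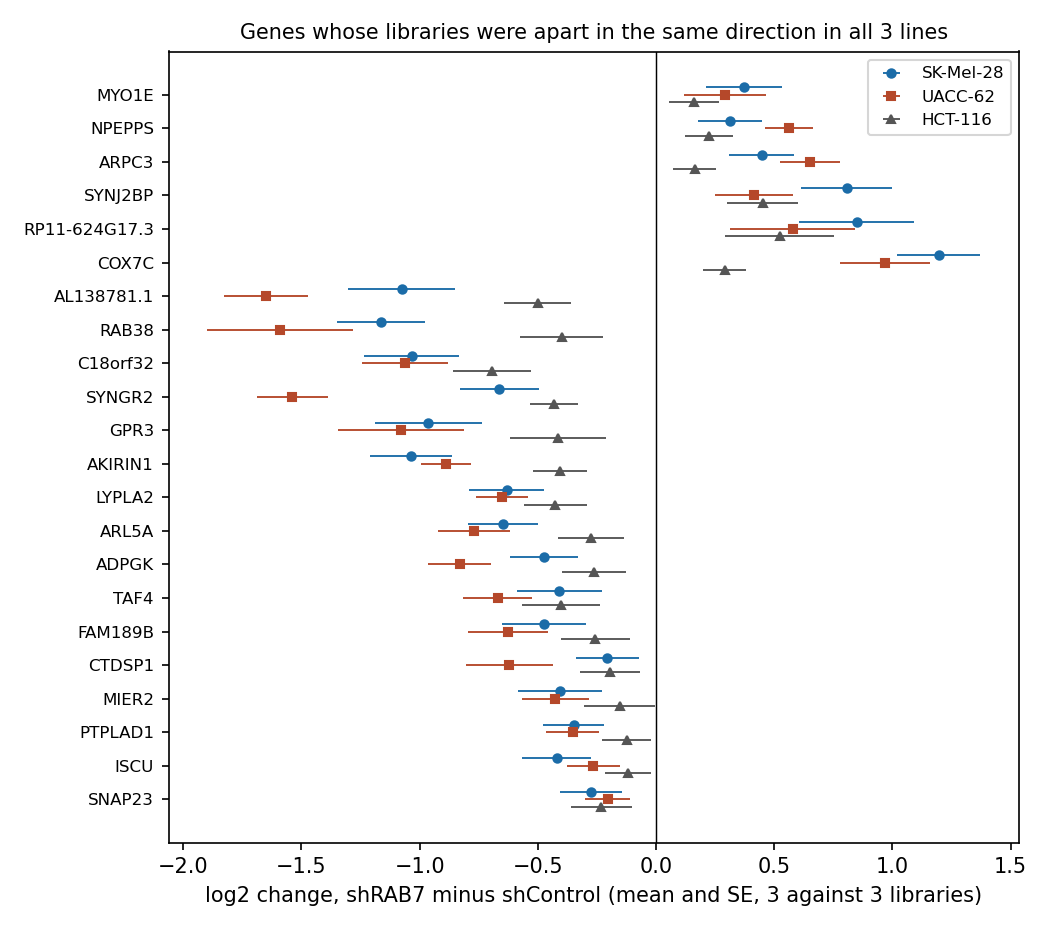
Log2 change (shRAB7 minus shControl, horizontal axis; points are means, bars the SE from 3 against 3 libraries) of the 16 genes lower and 6 genes higher in every shRAB7 library than in every control library in all 3 lines. RAB38 lay at −1.16, −1.59 and −0.40 and COX7C at 1.20, 0.97 and 0.29 in SK-Mel-28, in UACC-62 and in HCT-116. The HCT-116 values include the control library that held melanoma transcripts.

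Under control shRNA the lines differed widely, as lines of separate tissue origin do: 8253 of 13265 genes differed between the melanoma lines and HCT-116, 3688 higher and 4565 lower. The median log2 difference of all genes was −0.0966, and median-of-ratios scaling raised it by 0.0964. Which direction holds more calls may therefore depend on scaling. The largest differences by the naming rule were the mesenchymal and neural crest genes TNC (log2 difference 6.18, SE 0.54), VIM (6.04), TIMP3 (5.80) and S100B (5.40), with TNFRSF14 (5.73) and IFI16 (5.61), and, lower, the epithelial genes KRT19 (−9.02, SE 0.22), EPCAM (−7.85), S100A14 (−7.46), SPINT2 (−7.22) and SFN (−7.08), with CRABP2 (−7.01). EPCAM, an epithelial adhesion molecule, was at 207 to 243 FPKM in the HCT-116 controls and was listed at 0 in all melanoma controls. VIM, TIMP3 and TNFRSF14 are uncertain, since their loci overlap other genes. Without the HCT-116 control that held melanoma transcripts TNC was at 7.22, VIM at 7.11, TIMP3 at 6.64, S100B at 6.51, TNFRSF14 at 6.44 and IFI16 at 6.66, and 7453 genes were called.

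Camera called 12 of 22 lists in that comparison, 0 of them with an estimated correlation. The melanocyte list was higher in all 29 members (median 2.56; adjusted p = 1.82e-13, and 0.351 with an estimated correlation, or 0.0382 with the block), and the intestinal epithelial list lower in 12 of 13 (median −3.05; adjusted p = 4.61e-07, and 0.122 with an estimated correlation). Lysosomal genes were higher in the melanoma lines (35 higher, 6 lower, 15 not called; median 0.89; adjusted p = 4.31e-07), as were V-ATPase subunits (12 of 15; 0.55; adjusted p = 0.00225), autophagy (19 of 32; 0.49; adjusted p = 0.00195) and chaperones (17 of 22; 0.82; adjusted p = 1.53e-05), all with adjusted p = 0.351 with an estimated correlation. Cholesterol and lipid synthesis was lower (23 of 27; −1.02; adjusted p = 3.84e-05, and 0.351), as was the cell cycle list (34 of 45; −0.86; adjusted p = 5.8e-05, and 0.567 with an estimated correlation). The invasive (0.74), matrix (1.68), hypoxia (0.49) and histone (0.73) lists were higher with adjusted p of 0.0191, 0.0019, 0.0191 and 0.0294, and 0.567 with an estimated correlation. Interferon-stimulated genes (0.29, adjusted p = 0.0545) were called with the block alone (adjusted p = 0.0442, and 0.531 with an estimated correlation).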

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

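The tests of noisier libraries, melanoma RNA, weaker knockdown and a single replicate pair were chosen after the results they address were seen; the tests of scaling, expression level and regroupings were chosen before.

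The following results differed between lines by a direct test, the genes in the fit with the replicate block and the lists at a preset correlation alone. With an estimated correlation none of the lists differed (adjusted p = 0.619 against HCT-116 and 0.724 between the melanoma lines), and the matrix and melanocyte differences were not called without the HCT-116 control that held melanoma transcripts (adjusted p = 0.057 and 0.517). With the replicate block, the log2 change in the melanoma lines minus that in HCT-116 was −1.87 for RAB7A, −1.16 for RAD54L, −1.07 for TGOLN2, −0.98 for RAD51AP1, 0.79 for COX7C and 0.79 for TMX4. In the primary fit, without the block, 0 genes were called. With the block 0 were called with pseudocount 0.1, no filter or no mean-variance trend. The count was also 0 without SK-Mel-28 pair 1 or 2, UACC-62 pair 2 or 3 or HCT-116 pair 1. Other choices with the block gave 2 to 117 genes. The median differences of lists between the melanoma lines and HCT-116 were −0.63 for cell cycle, 0.22 for lysosome, 0.36 for matrix and 0.30 for melanocyte genes. Between SK-Mel-28 and UACC-62 they were 0.84 for cell cycle, 0.26 for cholesterol and lipid synthesis, 0.18 for ATF4, −0.29 for the invasive state, −0.19 for NF-kB targets, −0.21 for hypoxia and −0.44 for mitochondrially encoded transcripts.

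Splits of the 6 libraries of a line number 10, and within-pair swaps number 4, each with the real one included, which is too few for a share under 0.05. A real count of 0 is reached by all of them. For genes, the real value and the highest other were 3 and 0 in SK-Mel-28, 8 and 1 in UACC-62 and 0 and 1 in HCT-116, with 1, 1 and 10 of the 10 splits giving as many. With the block they were 42 and 1, 670 and 0, and 0 and 0, with 1, 1 and 4 of the 4 swaps giving as many. For lists they were 9 and 8, 7 and 14, and 3 and 10, with 1, 5 and 8 of 10 splits giving as many, and with the block 7 and 3, 8 and 3, and 3 and 4. The splits with more lists than the real one each part 1 pair and keep 2 pairs together, which points to the pairs as a structure of the samples. Among the splits that part all 3 pairs, the highest other was 0 genes in each line and 3 lists in each line.

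For the melanoma lines minus HCT-116, all 100 of 100 regroupings gave at least the real 0 genes, with a highest of 163. A real count of 0 fixes that outcome, so the test cannot decide for genes. For lists, 69 of 100 gave at least the real 4, with a highest of 13, so chance is not excluded. The 3 regroupings with most genes (163, 56 and 40) all exchanged HCT-116 shControl 3 with shRAB7 2. They set libraries with 14525 to 14786 detected genes against libraries with 13895 to 14153, a structure within HCT-116 apart from the shRNA. With the block 4 of 100 swaps gave at least the real 6 genes. This share, under 0.05, argues against chance for a response in the lines, since swaps remove the responses themselves. It does not test whether the lines differ, and the regrouping tests were not adjusted for their number. The other 3 gave 87, 49 and 25 genes. Up to the overall sign, these kept both melanoma responses whole and exchanged all HCT-116 pairs, pair 2, and pairs 1 and 3, so the real HCT-116 labels did not give the most genes. For SK-Mel-28 minus UACC-62, all 100 of 100 regroupings gave at least the real 0 genes (highest 1), 43 of 100 at least the real 7 lists (highest 14), and 32 of 32 swaps at least the real 0 genes with the block. The highest of these, 955, exchanged all SK-Mel-28 pairs and so added both responses. With a real count of 0 genes, both gene results were again fixed in advance. For the controls, 1 of 100 regroupings, the real one, gave as many as 8253 genes (highest other 6141). This argues against chance for differences between the lines. It does not test melanoma against HCT-116 in particular, since the regroupings shuffled single libraries over the lines. For lists, 20 of 100 gave as many as 12 (highest other 17), so chance is not excluded.

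The first pattern weighed is that 0 genes were called in HCT-116 against 670 in UACC-62 with the block, a contrast absent with no filter or no mean-variance trend, where UACC-62 also gave 0. Noisier HCT-116 libraries are argued against by their residual spread, which was 0.908 times that of UACC-62, and melanoma RNA in the HCT-116 control library of replicate 1 by the 0 genes called among those no higher in either melanoma line, where UACC-62 gave 239. Weaker knockdown with a proportional response is argued against by the slope of HCT-116 on UACC-62 changes, 0.00285 (SE 0.0747 over 3 pairs), where the RAB7A changes have a ratio of 0.244; over genes no higher in either melanoma line it was 0.0389 (SE 0.0399). This reading is not firm, since a 95% t interval over 3 pairs reached 0.324 over all genes, past the ratio, although it ended at 0.211 over the restricted ones, and since genes picked for their change in UACC-62 overstate it: the SK-Mel-28 slope, 0.323, also lay under its RAB7A ratio of 0.522. The RAB7A level left was 107 FPKM in HCT-116, 102 in SK-Mel-28, where 42 genes were called with the block, and 72.4 in UACC-62. A threshold on that level, a threshold on the relative reduction and a difference between melanoma and colorectal cells stay open, and 1 non-melanoma line cannot part them.

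The second pattern is the lower cell cycle list in UACC-62. Library scaling is argued against by medians of −1.01 or lower under median-of-ratios scaling and quantile normalization, and a single replicate pair by the highest pair median of −0.48. The expression level of the genes is argued against by 0 of 10000 lists matched on it that had so low a median (percentile 0). What lowers the list stays open, since no biological explanation was tested. Whether the pair with most RAB7A left (125 FPKM), which had the weakest change, shows a dose relation was not tested, since 3 pairs are too few.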

How the results depend on the processing

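Tests with the replicate block together with another choice, the one that treats failed estimates as missing and those without the HCT-116 library that held melanoma transcripts were chosen after the data were seen; all others before. No named gene changed direction. The medians of 3 lists called between SK-Mel-28 and UACC-62 crossed 0 in an alternative in which the list was not called: ATF4 (−0.01) without UACC-62 shRAB7 1, NF-kB targets (0.01) without SK-Mel-28 shRAB7 1, and, with the block, p53 targets (0.02) without SK-Mel-28 pair 1.

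Genes changed in SK-Mel-28 (3) became 1 with pseudocount 0.1, 0 with no filter, 22 with rows of other status kept and 42 with the replicate block, and ranged from 0 to 14 with a library left out. In UACC-62 (8) they became 0 with no filter, 18 with a minimum of 5 FPKM, 5 with median-of-ratios scaling, 25 with rows of other status kept, 1 with no mean-variance trend (higher, and not among the 8), 58 in 1 fit of all 18 libraries, 4 with failed estimates as missing and 670 with the block, and ranged from 0 to 361. In HCT-116 (0) they became 20 with rows of other status kept and 1 in 1 fit of all libraries, and ranged from 0 to 1. The 0 that differed between the melanoma lines and HCT-116 became 2 with rows of other status kept and 6 with the block, with a range of 0 to 1, and the 0 between SK-Mel-28 and UACC-62 became 3 and ranged from 0 to 1. The control comparison ranged from 7380 to 8476.

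With the replicate block, the 42 genes of SK-Mel-28 became 5 with pseudocount 0.1, 0 with no filter, 154 with a minimum of 5 FPKM, 1 with no mean-variance trend, 4 in 1 fit of all libraries and 3 without the block, and ranged from 0 to 339 with a pair left out. The 670 of UACC-62 became 0 with no filter, 0 with no trend and 8 without the block, and ranged from 32 to 739. The 0 of HCT-116 became 1 with a minimum of 5 FPKM, 1 with median-of-ratios scaling and 1 with quantile normalization, each time RAB7A (adjusted p = 0.016, 0.0339 and 0.0211). The 6 that differed between the melanoma lines and HCT-116 became 0 with pseudocount 0.1, 13 with pseudocount 5, 0 with no filter, 25 with a minimum of 5 FPKM, 3 with median-of-ratios scaling, 0 with no trend and 0 without the block. They ranged from 0 to 117 (117 without the UACC-62 pair of replicate 1; 0 without SK-Mel-28 pair 1 or 2, UACC-62 pair 2 or 3 or HCT-116 pair 1; 3 without HCT-116 pair 2; 2 without SK-Mel-28 or HCT-116 pair 3). Between SK-Mel-28 and UACC-62 they ranged from 0 to 84 (84 without UACC-62 pair 1, 40 without SK-Mel-28 pair 3). In UACC-62, 1 fit of all libraries with the block moved the share of calls that were higher from 41.6% to 24.7%.

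RAB7A kept its direction in every alternative. Its log2 change in SK-Mel-28 was −1.90 with pseudocount 0.1 and ranged from −2.13 to −1.71 with a library left out. There, its adjusted p rose past 0.05 with pseudocount 0.1 (0.0508), no filter (−1.89; 0.388), other status kept (0.192), no trend (0.0977), 1 fit of all libraries (0.0531), and without shControl 2 (0.189), shRAB7 2 (0.126) or shRAB7 3 (0.138). In UACC-62 (−3.62) it did so with no filter (0.161), other status kept (0.0788), no trend (0.065) and without each library but shRAB7 1 (0.051 to 0.234), with a range of −4.09 to −3.37. In HCT-116 (−0.88, range −0.94 to −0.82) it passed with other status kept (0.0384). With an estimated correlation 0 lists were called in SK-Mel-28, 0 in UACC-62 and 0 in HCT-116. Lists ranged from 6 to 10, 6 to 10 and 1 to 9 with a library left out (HCT-116: 1 without shControl 1, 9 without shControl 3, 5 without shRAB7 2). The 2 genes shared by the melanoma lines became 1 with pseudocount 0.1, 0 with no filter, 0 with no trend and 17 with the block. These 17 became 5 with pseudocount 0.1, 0 with no filter, 58 with a minimum of 5 FPKM, 0 with no trend, 3 in 1 fit and 2 without the block. SK-Mel-28 and HCT-116, and UACC-62 and HCT-116, shared 0 genes with the block, and 1 each with a minimum of 5 FPKM, median-of-ratios scaling and quantile normalization.

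With no filter more genes were tested, and the counts of SK-Mel-28 and UACC-62 fell. The cause of this fall and of the other moves was not tested. The 12 named genes of the control comparison stayed called throughout. All 6 other calls of named genes without the block beside RAB7A (5 genes, TGOLN2 in both melanoma lines) were lost in at least 1 alternative, as were all 69 with it (58 genes, some in more than 1 comparison). With an estimated correlation the melanocyte list of the control comparison, with the block, was alone in staying called. Beyond the calls given here and beside the results, the block changed no other call of a result reported on all libraries. Scaling moved the median of all genes by less than 0.1 on the log2 scale. The median gene at or above 1 FPKM rested on at most 114 implied fragments, and genes near 1 FPKM rested on fewer. The correlation of log2 changes between SK-Mel-28 and UACC-62 (0.303) became 0.230 with pseudocount 0.1, 0.368 with pseudocount 5, 0.198 with no filter, 0.393 with a minimum of 5 FPKM and 0.0638 with rows of other status kept. That between SK-Mel-28 and HCT-116 (0.036) became 0.0959 with a minimum of 5 FPKM and −0.0238 with rows of other status kept, and that between UACC-62 and HCT-116 stayed between −0.0273 and 0.0516.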

Other observations

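The test of the regroupings and of the seed matches was chosen before its result was seen, and the full enumeration of regroupings after it.

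Several pathways that respond to endosomal or nutrient stress were not called in any line. Autophagy genes had median log2 changes of 0.05, 0.06 and 0.01 in SK-Mel-28, in UACC-62 and in HCT-116 and were not called (adjusted p = 0.34, 0.256 and 0.95), although with the block BNIP3, a mitophagy receptor, rose in UACC-62 (28.5 ± 5.91 to 42.9 ± 4.68 FPKM, n = 3; log2 change 0.59, adjusted p = 0.0188) and ATG4D, a protease that processes ATG8 proteins and whose locus overlaps another gene, fell by 0.52 on the log2 scale. ATF4 and amino acid response genes were at 0.11, −0.06 and 0.01, and differed between SK-Mel-28 and UACC-62 (0.18, adjusted p = 0.0388, and 0.724 with an estimated correlation); with the block the amino acid transporters went apart in UACC-62, SLC1A4 up by 0.41 and SLC7A5 down (−0.37). MAPK pathway output was at −0.13, −0.06 and −0.01 (adjusted p = 0.0834, 0.863 and 0.625). In SK-Mel-28 the ATF4 and MAPK medians lay at percentiles 99.7 and 1.22 of 10000 lists matched on expression level. With the block the MAPK members EGR1 (−0.48) and SPRY4 (0.48, overlapping locus) were called in UACC-62.

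Interferon-stimulated genes, which can respond to lentivirus or double-stranded RNA, were at 0.06, 0.01 and 0.03 in the 3 lines and were not called. Control cells were infected with an shRNA lentivirus too, so a response common to both groups would not show in this difference. Apoptosis regulators were at −0.05, 0.00 and 0.03, with the survivin gene BIRC5 (−1.13, SE 0.23) and BCL2A1 (−0.47) lower in UACC-62 with the block, and NF-kB targets there were at 0.07, with ICAM1 at 0.34. In SK-Mel-28, p53 targets (0.10), chaperones (0.05) and hypoxia genes (0.00) were not called. Fibroblast and smooth muscle markers were tested in UACC-62 (0.17 over 6 members) and HCT-116 (0.08 over 5) and were not called. Replication-dependent histones were at 0.04 in UACC-62 and 0.05 in HCT-116. Median, mean and test differed in sign for Rab GTPases in UACC-62 and HCT-116, for late endosome machinery, melanocyte and apoptosis lists in UACC-62, for V-ATPase and ATF4 lists in HCT-116, and for 5 and 2 uncalled lists in the 2 comparisons of responses.

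The third pattern is the set of 16 genes that lay lower in all 3 lines beside RAB7A. Chance among all genes tested is argued against, since 1 of 100 regroupings within lines, the real one, had as many (highest other 15), and of all 8000 regroupings 28 had, and of the 512 that part all 9 pairs 1, with a highest other of 6. The regroupings with as many or more, up to 41, keep at least 1 pair together and so hold the differences between replicates. The guide's seed is not known, since the labels give a target of 14 bases alone; the 8 seeds searched are those allowed by an assumed target of 21 bases that holds them. For these, seed matches of the shRNA guide are argued against as the cause of the whole set. The smallest of 8 Bonferroni-adjusted Fisher exact p was 1, and of 15 genes with a searched 3′ UTR 5 (33.3%) held the best match, against 1726 of 7833 others. Seeds of a target of another length, other effects of the shRNA on transcripts and a shared response to RAB7 loss stay open, since 1 shRNA was used. The part of the HCT-116 control library that held melanoma transcripts was not tested either, since the set was not recomputed without it.

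All rows of the mitochondrial chromosome, a wider set than the mitochondrial list, made up 6.01% to 8.97% of FPKM in UACC-62 libraries and 5.62% to 6.46% in HCT-116 libraries. Of 26 melanocyte list members measured at 10 FPKM or more in a melanoma line, 15 were highest of the 6 HCT-116 libraries in shControl 1, where 4.33 would be if these were alike.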
